A study of Mus musculus with 12 samples.

How the data were processed

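Smart-seq2 RNA-seq libraries were made from sorted mouse testis cells of 2 stages, MII spermatocytes and round spermatids, and 2 genotypes, wildtype and a germ cell knockout of Pan2 (one deleted and one floxed allele with Stra8-Cre). Per the labels' protocols, polyadenylated RNA was primed with oligo(dT), preamplified, and made into libraries that were sequenced as paired reads on an Illumina instrument. Priming on poly(A) tails means that a change in tail length could change how well a transcript is captured, so counts are not a measure of tail length or of translation. The labels gave every library its group and replicate number, with 3 libraries in each of 4 groups.

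The authors deposited 1 table of whole-number counts per gene, with 55291 gene symbols and 12 libraries. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, STAR 2.7.10a, featureCounts 2.0.2 and DESeq2, and the genome build was mm10. Their order and settings, the annotation release, the strand setting and the treatment of reads with several positions are not given in the sources used here. Genes with near-identical copies, and antisense or overlapping genes, are therefore uncertain. Coordinates and exon lengths came from the deposited table. GC content and gene type (such as protein-coding) came from the mm10 annotation GENCODE M21, in which 53292 of the symbols were found.

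The deposited counts were used as they are. Of 37839 genes with a count in any library, 21291 passed edgeR's filterByExpr (minimum count 10, minimum total count 15) and were tested. Library sizes were scaled with the TMM method, and CPM values use these scaled sizes. The main test was edgeR's quasi-likelihood F test with robust estimation, fitted to all 12 libraries with a mean for each of the 4 groups and 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. The 5 comparisons were KO with WT in MII, KO with WT in RS, the difference between these effects, and RS with MII in WT and in KO. With 3 libraries per group an exact permutation test of 1 gene cannot go below p = 0.1, so single genes were tested only in the model across all genes.

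The comparisons, their tests, the named-gene rule, the 28 gene lists (7 of them cell type markers) and the alternatives named next, with the exceptions stated there, were fixed before the data were examined. Each list was described by its called members, by its members called when p was adjusted over the list alone, by the median log2 fold change, and by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Named genes were Pan2, and per KO comparison the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM over the 6 libraries and no overlap between groups, without predicted genes and pseudogene symbols. They also included up to 4 members with the smallest adjusted p of each list with a call, or 2 of a list without one. For RS against MII in WT the numbers were 8 each way at 20 CPM and 3 per list, and for the difference 5 each way. The texts give a part of these genes and say where a gene was chosen after its values were seen.

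Alternatives were DESeq2's size factors, the total count without a composition factor, no filter, a filter of 5 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, only the 6 libraries compared, leaving out mitochondrial genes and the 10 genes with the most counts, a fold change of at least 2, and leaving out each library in turn. Sertoli and Leydig marker scores as covariates, counts of protein-coding genes, the sex chromosome sets, the agreement of stage changes between WT and KO, and the gene list tests under alternatives other than the estimated correlation, fry, the replicate block and DESeq2's size factors were added after the data were seen. Principal components were computed on log2 CPM with a prior count of 2.

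The tests were checked on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed. For KO against WT in MII (20692 genes in the step), 5.97% of genes changed 1.5-fold, 40.9% of those changed 2-fold and 78.3% of those changed 4-fold were recovered, and 3.70% of calls were false. For RS (20694 genes) the shares were 10.8%, 50.9% and 76.5%, with 6.38% false. For the difference (20671 genes) they were 0%, 11.4% and 59.3%, with 0% false, and for RS against MII in WT (20678 genes) 7.94%, 40.9% and 77.4%, with 2.44% false. A list of 30 genes raised 1.5-fold in RS was called by camera with the preset (5.57e-22) and the estimated correlation (7.29e-05), and 0 of 20 random lists were called. Only 200 genes were changed, so the adjusted threshold was stricter there than in a comparison that calls many genes. The shares recovered do not carry over to such a comparison. Simulated genes were drawn independently of each other. The check therefore cannot show whether the preset correlation is high enough for genes that vary together in the real libraries.

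The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.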

Results

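The transcriptomes of spermatocytes at the MII stage and of round spermatids (RS), the haploid cells that follow meiosis, were measured in wildtype (WT) mice and in mice that lack PAN2 in germ cells (KO). PAN2 is the catalytic subunit of a deadenylase, an enzyme complex that shortens the poly(A) tails of mRNAs. In the knockout, 1 allele of Pan2 was deleted and the other was flanked by loxP sites and removed by a Cre recombinase driven from the Stra8 promoter, which is active in germ cells around the entry into meiosis. Each of the 4 groups had 3 libraries, 12 in all, made from sorted cells with Smart-seq2. The total count per library was between 13781370 and 38652066. The 3 WT MII libraries held 13781370, 21427227 and 34436668 counts, the KO MII libraries 24207417, 38652066 and 23056376, the WT RS libraries 34057646, 32068535 and 26548977, and the libraries labelled KO RS 31862857, 29218445 and 24326972. Counts were summed per gene, 21291 genes were tested, and the biological coefficient of variation between libraries of a group was 22.28%. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

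The comparison of KO with WT libraries asked which transcripts depend on PAN2 before and after the end of meiosis, and Pan2 itself came ahead of all other genes as a check of the labels. Pan2 lies on chromosome 10, from 128303335 to 128321358 on the plus strand of mm10, with 23 merged exons. In MII libraries Pan2 was at 14.4 ± 2.34 CPM (counts scaled to a common library size, mean ± SD, n = 3) in WT and at 5.92 ± 1.06 CPM in KO, with no overlap between the groups. The log2 fold change was -1.28 (SE 0.549) and did not pass the test across all genes (edgeR quasi-likelihood test, adjusted p = 0.227). It passed without the library labelled KO RS replicate 1 (0.00469) and when only the 6 MII libraries were fitted (0.00741). With the Sertoli and Leydig marker scores as covariates, a setting chosen after the data were seen, it was -3.10 (adjusted p = 0.00692). WT RS libraries had 9.93, 8.13 and 12.95 CPM of Pan2. The libraries labelled KO RS replicate 2 and replicate 3 had 4.73 and 3.52 CPM, below every WT RS library, whereas the library labelled KO RS replicate 1 had 22.57 CPM, the highest of the 12 libraries. The fitted change in RS was therefore 0.003 (SE 0.533, adjusted p = 0.998), and -1.32 with an adjusted p of 0.00782 when the library labelled KO RS replicate 1 was left out. Pan2 thus went against the label of that library. The count covers all exons of the gene, including those outside the floxed part, and which exons are floxed is not given in the sources used here, so it checks the deletion only in part.

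**Figure D1:**
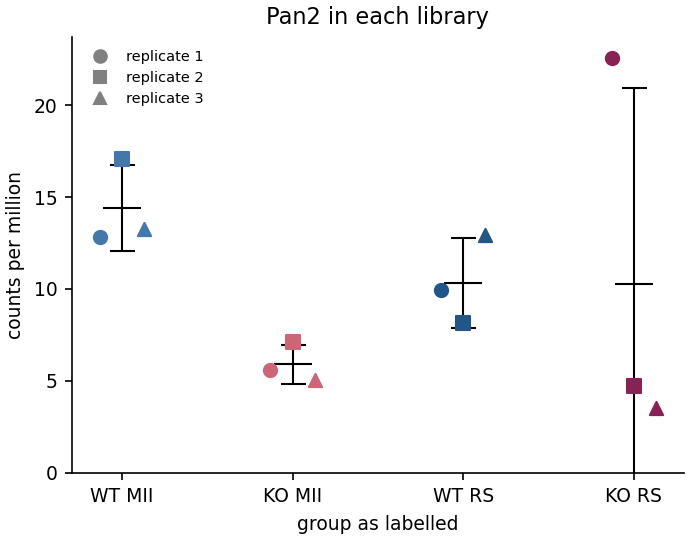
Pan2 in each library, in CPM, by group as labelled. Points are libraries, long bars are means and whiskers are 1 SD (n = 3 per group, drawn down to 0 for KO RS). The library labelled KO RS replicate 1 stands at 22.57 CPM, and the other 2 libraries of its group at 4.73 and 3.52 CPM.

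Stage and genotype both separated the libraries. The leading principal component of log2 CPM carried 31.04% of the variance and set MII libraries apart from RS libraries. The next component carried 23.37% and placed all 6 WT libraries between 32.07 and 56.22 and all 6 KO libraries between -68.23 and -16.50. The library labelled KO RS replicate 1 was at -68.23, on the KO side and farthest from WT. Libraries of a group correlated between 0.965 and 0.983 (Pearson, log2 CPM across genes, which are not independent replicates), and every pair differed by more than sampling noise (chi-square per degree of freedom between 8.60 and 81.9), so no library was taken for another one deposited again. Repeat preparations of 1 sample could differ by as much, so this does not show that the samples were separate.

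**Figure D2:**
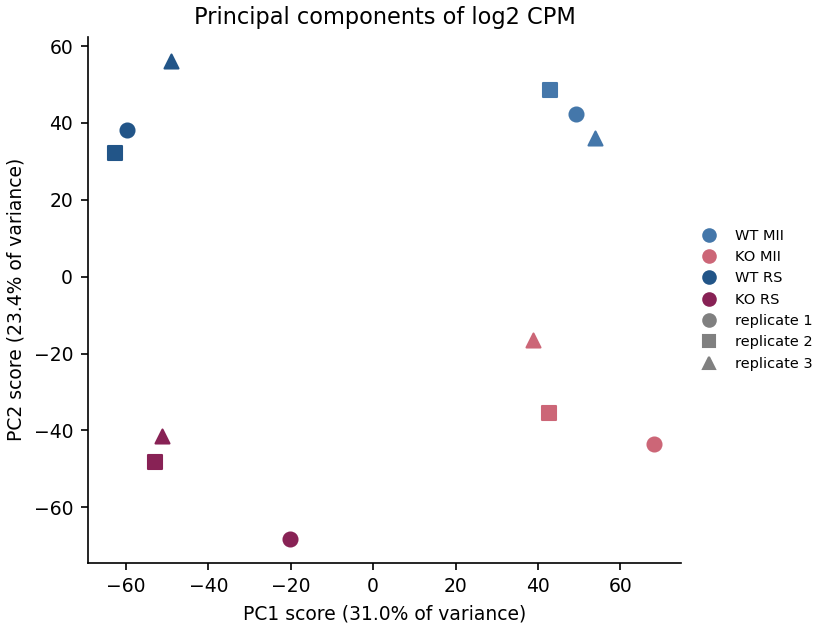
Scores of the 12 libraries on the leading 2 principal components of log2 CPM, without units, with the percent of variance on each axis. Color gives the group as labelled and the marker shape the replicate number. The horizontal axis (31.04%) separates the stages and the vertical axis (23.37%) the genotypes.

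Transcripts of somatic testis cells were present in the sorted fractions, and those of Sertoli and Leydig cells were higher in KO libraries. Sertoli cells nurse the germ cells within the tubule, and the summed CPM of their 22 tested markers was 37.3, 53.1 and 62.6 in WT MII, 525, 255 and 127 in KO MII, 12.7, 11.3 and 15.5 in WT RS, and 373, 60.8 and 93.9 in the libraries labelled KO RS, with replicate 1 the highest. Leydig cells make testosterone outside the tubule. Their 15 markers summed to 169, 156 and 162 CPM in WT MII, 567, 340 and 296 CPM in KO MII, 5.84, 4.62 and 5.24 CPM in WT RS and 54.9, 19.5 and 10.3 CPM in the libraries labelled KO RS. Clu, a Sertoli marker, was at 10.7 ± 5.51 CPM (mean ± SD, n = 3) in WT MII and at 200.4, 104.7 and 48.8 CPM in KO MII libraries. It was at 1.36 ± 0.246 CPM in WT RS libraries and at 157.6, 22.1 and 34.4 CPM in the libraries labelled KO RS replicate 1, 2 and 3. The sum for peritubular myoid, endothelial and stromal cells was 156 CPM in WT and 120 CPM in KO MII libraries, and 19.4 CPM in WT and 33.6 CPM in KO RS libraries. These sums differed between genotypes in the same libraries as the gene groups described next.

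**Figure D3:**
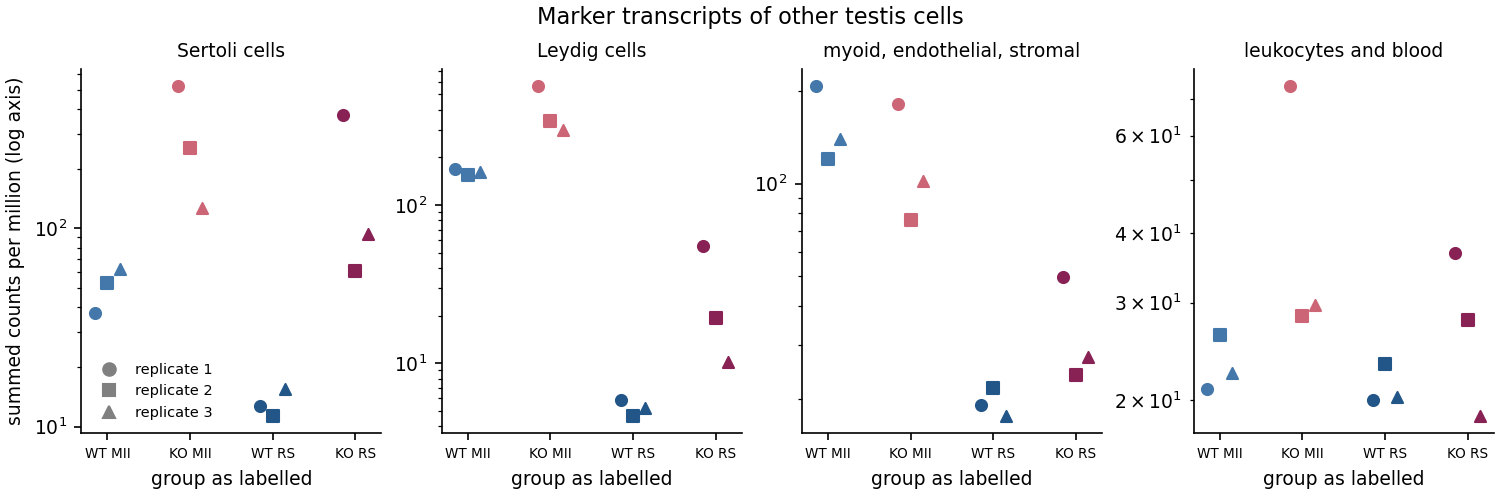
Summed CPM (log axis) of the marker transcripts of 4 somatic cell classes in each of the 12 libraries, by group as labelled. Points are libraries and the marker shape gives the replicate number. The Sertoli sum is 127 to 525 CPM in KO MII libraries against 37.3 to 62.6 CPM in WT MII libraries.

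In the MII libraries, transcripts of Prm1, Prm2 and Tnp2, which encode proteins that package sperm DNA, were lower in KO than in WT. The 20 markers of elongating and condensing spermatids summed to 11200 CPM in WT MII and 12900 CPM in WT RS libraries. In KO they summed to 9350 and 10400 CPM. Spermatid transcripts were thus abundant in the MII fraction, and changes of spermatid genes there cannot be assigned to MII spermatocytes alone. The Sertoli marker sum of the MII libraries was 127 to 525 CPM in KO against 37.3 to 62.6 CPM in WT. Prm1 (chromosome 16, 10796326 to 10805839, minus strand), which encodes a protamine that replaces histones in the sperm nucleus, fell from 1364 ± 281 to 389 ± 162 CPM (mean ± SD, n = 3), a log2 fold change of -1.81 (SE 0.246, edgeR adjusted p = 0.0011). Its neighbours Prm2, the other protamine, and Tnp2, a transition protein that binds DNA before the protamines do, changed by -1.36 (SE 0.202, adjusted p = 0.00131) and -1.65 (SE 0.226, adjusted p = 0.000808). Of the other members of these families, chosen after their values were seen, Tnp1 was at -1.03 (adjusted p = 0.0178), a call lost without WT MII replicate 1 (0.0515) or 3 (0.0794) or KO MII replicate 2 (0.103) or 3 (0.0621), and Prm3 was at -0.20 (adjusted p = 0.749). Transcripts of Dazl, a germ cell RNA-binding protein that acts on translation, rose from 13.4 ± 1.66 to 31.8 ± 11.8 CPM (log2 fold change 1.24, SE 0.224, adjusted p = 0.00483). Acta2 and Myh11, contractile proteins of smooth muscle and myoid cells, had log2 fold changes of -2.28 (adjusted p = 0.000664) and -3.92 (adjusted p = 0.000504). All of these calls except that of Tnp1 held when any 1 of the 12 libraries was left out, with Myh11 at -4.69 without KO MII replicate 3. With the marker covariates the calls of Dazl (0.545, adjusted p = 0.768) and Myh11 (-3.75, adjusted p = 0.198) were lost, and those of Prm1, Prm2, Tnp2 and Acta2 stayed. In RS, Dazl was at 0.75 (adjusted p = 0.0291), lost without WT RS replicate 1 or 3 or the libraries labelled KO RS replicate 1 or 2.

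Across all genes, 389 were higher and 395 lower in KO MII libraries (784 of 21291), and 375 of them changed at least 2-fold, 126 up and 249 down. Among genes named by the fixed rule and called without any 1 library, Car2, a carbonic anhydrase, fell by 1.76, Tex46 by 2.91 and Esyt3 by 1.93, and Msmo1, an enzyme of cholesterol synthesis, rose by 1.87 and Slco5a1 by 1.61 on the log2 scale (adjusted p between 0.000504 and 0.00345). With the marker covariates the calls of Msmo1 (1.37, adjusted p = 0.51), Slco5a1 (1.27, adjusted p = 0.511) and Tex46 (-3.14, adjusted p = 0.0702) were lost. Those of Car2 and Esyt3 stayed. Klk1b8 (-2.18) and Hmgb1-rs17 (-2.65) were lower too, but both may share reads with near-identical genes and are uncertain. Kcnab1, a potassium channel subunit, was higher by 1.39 (adjusted p = 0.0112), a call lost without WT MII replicate 3 (0.0635) or KO MII replicate 2 (0.0534). The count was 264 without WT MII replicate 3, 272, 147 and 458 without KO MII replicate 1, 2 and 3, and 469 without WT RS replicate 1. The near balance of rises and falls shifted to 287 higher and 597 lower without WT MII replicate 2, 69 and 203 without KO MII replicate 1, 45 and 102 without KO MII replicate 2, and 333 and 472 when scaled by the total count alone. Among protein-coding genes, a set chosen after the data were seen, it was 341 and 250. It was 40, with 0 higher, when the Sertoli and Leydig marker scores entered as covariates, and DESeq2 called 1455 genes and limma-voom 830.

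In MII libraries, 4 lists of spermatid genes passed camera with the preset correlation and not with an estimated one. Of 67 acrosome genes, which build the enzyme-filled cap of the sperm head, 6 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 5.4e-05, and adjusted p = 0.234 with an estimated correlation). Of 122 flagellum, axoneme and manchette genes, 7 were higher and 1 lower (17 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.00036, and adjusted p = 0.234 with an estimated correlation). All 23 sex-linked multicopy spermatid genes had positive values, 3 of them called (9 adjusted over the list alone, median 0.44, camera adjusted p = 5.64e-07, and adjusted p = 0.317 with an estimated correlation). Their median was near that of all 790 tested X-linked genes (0.48). These genes have near-identical copies that may share reads. Of 20 markers of elongating and condensing spermatids, 6 were lower and 0 higher (7 and 3 adjusted over the list alone, median -0.15, camera adjusted p = 0.000588, and adjusted p = 0.55 with an estimated correlation). Spam1, the hyaluronidase of the acrosome, was higher by 0.81 (adjusted p = 0.0188), but not past the threshold without KO MII replicate 1 (0.0543) or replicate 2 (0.114). Tssk6, a kinase of condensing spermatids and a member of the elongating spermatid list, had a log2 fold change of -1.06 (adjusted p = 0.00842), lost without KO MII replicate 2 (0.07).

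Further lists passed camera in MII but lost the call without single libraries. The protamine, transition protein and chromatin list had 5 of 38 genes lower and 0 higher (5 and 1 adjusted over the list alone, median -0.04, camera adjusted p = 0.0447, and adjusted p = 0.234 with an estimated correlation). The call was lost without WT MII replicate 1 (0.0841) or 2 (0.0731), KO MII replicate 2 (0.119) or 3 (0.0978), or the library labelled KO RS replicate 2 (0.0534). The sperm mitochondrial sheath and energy metabolism list had 2 of 42 genes higher (6 higher and 1 lower adjusted over the list alone, median 0.14, camera adjusted p = 0.0324, and adjusted p = 0.234 with an estimated correlation). That call was lost without WT MII replicate 2 (0.0674), KO MII replicate 1 (0.0712) or 3 (0.0646), or KO RS replicate 2 (0.0542). Nuclear genes of oxidative phosphorylation had 3 of 75 lower (also 3 adjusted over the list alone, median -0.20, camera adjusted p = 0.000588, and adjusted p = 0.622 with an estimated correlation). The lowest adjusted p of these was that of Uqcrh, a subunit of respiratory complex III (-0.63, adjusted p = 0.0188), lost without WT MII replicate 3 (0.0632) or KO MII replicate 1 (0.0634) or 2 (0.0857) and with only the 6 MII libraries (0.0516). The 13 mitochondrially encoded transcripts had 0 called by edgeR (3 higher adjusted over the list alone) with a median of 0.42 (camera adjusted p = 0.00219, and adjusted p = 0.509 with an estimated correlation). Both list calls were lost without WT MII replicate 3 (0.63 and 0.0834). Of the 12 libraries, that one had the lowest share of mitochondrial counts (0.21%) and of ribosomal RNA counts (0.06%). Meiotic prophase genes had 1 of 47 higher (also 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.0447, and adjusted p = 0.386 with an estimated correlation), and the call was lost without WT MII replicate 2 (0.101) or 3 (0.0995), KO MII replicate 1 (0.118) or 2 (0.128), WT RS replicate 2 (0.0507) or 3 (0.0574), or KO RS replicate 2 (0.0534).

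Among somatic and early germ cell markers in MII libraries, 3 of 22 Sertoli genes were higher (15 adjusted over the list alone, median 2.35, camera adjusted p = 4.96e-10), as were 3 of 15 Leydig genes (9 adjusted over the list alone, median 1.43, camera adjusted p = 4.45e-07). Of 18 peritubular myoid, endothelial and stromal genes, 3 were lower (also 3 adjusted over the list alone, median -0.53, camera adjusted p = 9.06e-05). With an estimated correlation the adjusted p was 0.239 for Sertoli genes and 0.234 for the other 2 lists. The list of macrophages, other leukocytes and blood had 1 of 15 higher (4 adjusted over the list alone, median 1.36, camera adjusted p = 0.00467, and adjusted p = 0.386 with an estimated correlation). It was lost without KO MII replicate 1 (0.062). Spermatogonia genes had 1 of 20 higher (also 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.0137, and adjusted p = 0.547 with an estimated correlation). It was lost without WT MII replicate 2 (0.0706) or KO MII replicate 1 (0.239). The leptotene to pachytene markers had 0 of 22 called (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.667), with a median of -0.06 while the test pointed up.

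The lists closest to the function of PAN2 held few calls in MII libraries. None of the 24 deadenylase genes was called by edgeR (also 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.624). Of 39 poly(A) binding and polyadenylation genes, Tent5d, a noncanonical poly(A) polymerase, was the 1 higher (also 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.226). Its log2 fold change was 0.86 (adjusted p = 0.0167), lost without WT MII replicate 3 (0.0683) or KO MII replicate 2 (0.103) and with only the 6 MII libraries (0.0588). Decapping genes had 1 of 22 lower (3 higher and 3 lower adjusted over the list alone, median -0.25, camera adjusted p = 0.533). Exosome and nonsense-mediated decay genes had 1 of 27 lower (also 1 adjusted over the list alone, median -0.04, camera adjusted p = 0.964). Cytosolic ribosomal proteins had 1 of 84 lower (0 adjusted over the list alone, median -0.01, camera adjusted p = 0.814). Translation factors had 1 of 54 higher (also 1 adjusted over the list alone, median 0.05, camera adjusted p = 0.397). Translational control genes had 1 of 48 higher, Dazl (also 1 adjusted over the list alone, median -0.07, camera adjusted p = 0.605). Germ cell transcription factors had 1 of 35 higher, Taf7l (also 1 adjusted over the list alone, median 0.11, camera adjusted p = 0.0912). Taf7l rose by 0.80 on the log2 scale (adjusted p = 0.00844), a call lost without KO MII replicate 1 (0.0571). Tent5d and Taf7l both lie on the X chromosome. Its 790 tested genes had a median of 0.48 in MII, with 87 higher and 0 lower.

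Meiotic division genes had 1 of 56 lower in MII libraries (also 1 adjusted over the list alone, median -0.02, camera adjusted p = 0.234). It was Bub3, a spindle checkpoint protein (-0.68, adjusted p = 0.026), lost without WT MII replicate 3 (0.0838) or KO MII replicate 1 (0.0898), 2 (0.102) or 3 (0.0583). Stress response genes had 2 of 32 higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.964), with a median of 0.04 while the test pointed down. Ubiquitin, proteasome and autophagy genes had 1 of 59 higher (also 1 adjusted over the list alone, median -0.04, camera adjusted p = 0.964). The piRNA pathway genes (29 tested) and the p53 and apoptosis genes (30 tested) had 0 called, also when adjusted over the list alone, with medians of 0.03 and 0.17 (camera adjusted p = 0.461 and 0.49).

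In round spermatids, 7 of the 38 genes of the protamine, transition protein and chromatin list were lower and 1 was higher in the libraries labelled KO (camera adjusted p = 0.00406, and adjusted p = 0.137 with an estimated correlation). The Sertoli marker sum was 60.8 to 373 CPM in these libraries against 11.3 to 15.5 CPM in WT. Prm1 fell from 1648 ± 391 to 258 ± 44.3 CPM (n = 3, log2 fold change -2.68, SE 0.254, edgeR adjusted p = 7.46e-06), Prm2 from 1457 ± 352 to 286 ± 47.1 CPM (-2.35, SE 0.208, adjusted p = 2.19e-06) and Tnp2 from 1293 ± 319 to 275 ± 48.6 CPM (-2.23, SE 0.231, adjusted p = 9.52e-06). Of the other members of these families, chosen after their values were seen, Tnp1 fell by 1.33 on the log2 scale (adjusted p = 0.00122), whereas Prm3 was at 0.21 (adjusted p = 0.672). Of 67 acrosome genes 17 were higher and 2 lower (camera adjusted p = 6.02e-06, and adjusted p = 0.506 with an estimated correlation). Spam1 rose from 183 ± 31.7 to 364 ± 27.8 CPM (log2 fold change 0.99, SE 0.179, adjusted p = 0.00194) and Acrv1, an acrosomal vesicle protein, from 637 ± 139 to 1041 ± 82.8 CPM (0.71, SE 0.15, adjusted p = 0.00513). All of these calls held without any 1 library, the library labelled KO RS replicate 1 included, whose Pan2 count goes against its label. With the marker covariates the calls of Spam1 (0.97, adjusted p = 0.309) and Acrv1 (0.65, adjusted p = 0.477) were lost, and those of Prm1, Prm2 and Tnp2 stayed.

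**Figure D4:**
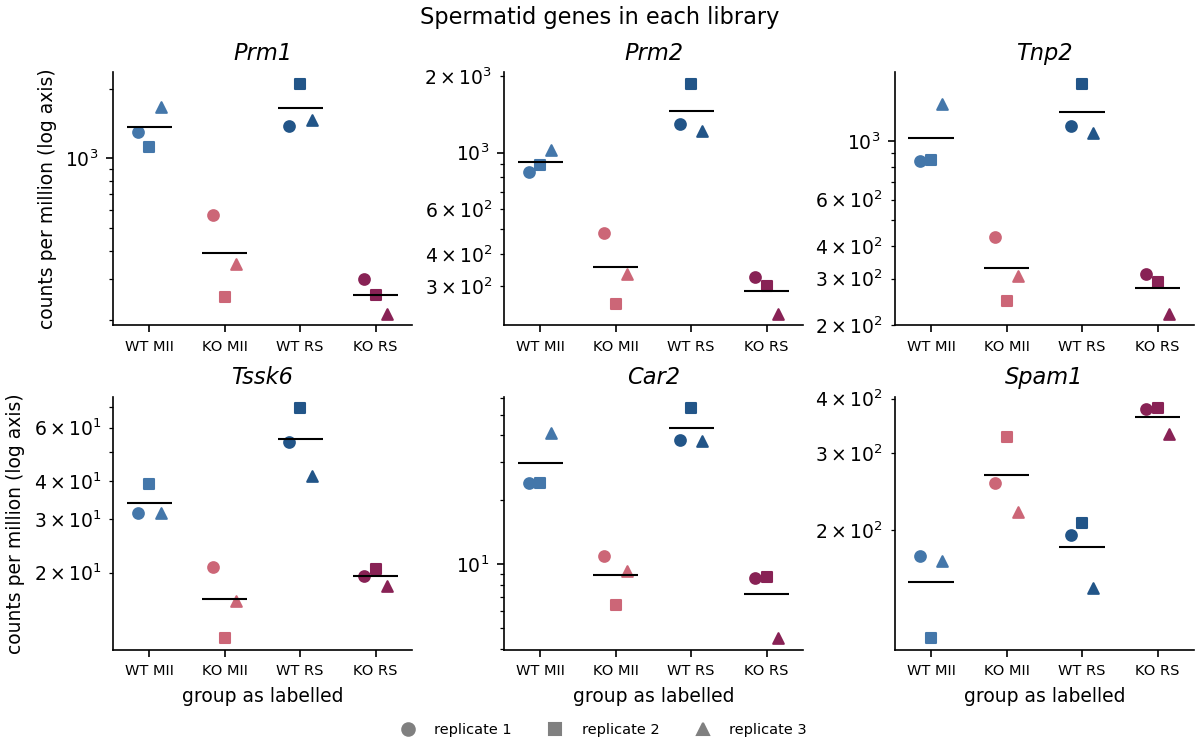
CPM (log axis, range set per panel) of 6 spermatid genes in each of the 12 libraries, by group as labelled. Points are libraries, the marker shape gives the replicate number and bars are group means (n = 3). Prm1, Prm2, Tnp2, Tssk6 and Car2 are lower and Spam1 is higher in every KO library than in every WT library of the same stage.

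Across all genes, 1290 were higher and 1573 lower in the libraries labelled KO RS (2863 of 21291), and 1177 of them changed at least 2-fold, 494 up and 683 down. Falls that held without any 1 library included Tex46 (-3.27), Esyt3 (-3.24), Plekho2 (-3.09), Nqo2, a quinone reductase (-3.01), Car2 (-2.57) and Tssk6 (-1.50), with adjusted p between 1.79e-06 and 0.000159. Hmgb1-rs17 (-3.04) is uncertain because it may share reads. Among the rises, Slco5a1 (1.62, adjusted p = 0.000748) and Tmtc4 (1.57, adjusted p = 0.000329) held likewise. With the marker covariates the calls of Slco5a1 (1.25, adjusted p = 0.37) and Tmtc4 (1.18, adjusted p = 0.325) were lost, and those of the falls named here stayed. The Sertoli genes Clu (5.72), Defb19 (5.20) and Ctsl (4.75) passed with adjusted p of 0.00917, 0.00895 and 0.0115, but not without WT RS replicate 3 (0.0501, 0.0654 and 0.0634), and were at 4.38, 4.02 and 3.48 without the library labelled KO RS replicate 1. The count was 1483 (431 higher and 1052 lower) and 1139 (320 and 819) without WT RS replicate 1 and 3, and 1080 (366 and 714) and 1347 (536 and 811) without the libraries labelled KO RS replicate 1 and 2. Scaling by the total count alone gave 1014 higher and 1953 lower, and 106 genes were called (4 higher) with the Sertoli and Leydig marker scores as covariates.

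Of 56 genes of the meiotic divisions, 17 were lower and 0 higher in round spermatids (21 and 1 adjusted over the list alone, median -0.31, camera adjusted p = 3.7e-06, and adjusted p = 0.635 with an estimated correlation). Bub3 fell from 54.1 ± 10.4 to 19.99 ± 1.43 CPM (log2 fold change -1.43, SE 0.166, adjusted p = 2.74e-05). Cdc20, the activator of the anaphase-promoting complex, fell by 1.33, Aurkb, a kinase of chromosome segregation, by 1.25 and its partner Cdca8 by 1.08 on the log2 scale (adjusted p between 0.000223 and 0.00189). In the protamine, transition protein and chromatin list 7 of 38 were lower and 1 higher (9 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.00406, and adjusted p = 0.137 with an estimated correlation). Of 67 acrosome genes 17 were higher and 2 lower (26 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 6.02e-06, and adjusted p = 0.506 with an estimated correlation), among them Adam26a (0.76) and Tmem95 (0.66). All 23 sex-linked multicopy spermatid genes had positive values and 10 were called (16 adjusted over the list alone, median 0.68, camera adjusted p = 3.13e-08, and adjusted p = 0.506 with an estimated correlation), with Cypt2 at 0.98 (adjusted p = 0.00171), and reads that copies may share make single members uncertain. With the preset correlation these 4 calls held without any 1 library. The median of the sex-linked list was near that of all 790 tested X-linked genes (0.67).

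The markers of elongating and condensing spermatids split in round spermatids. Of 20, 7 were lower and 0 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.000192, and adjusted p = 0.723 with an estimated correlation). Their median was 0.10 while the test pointed down, and the call was lost without WT RS replicate 2 (0.0532). Cytosolic ribosomal proteins had 4 of 84 higher and 2 lower (4 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.00609, and adjusted p = 0.723 with an estimated correlation). That call was lost without WT RS replicate 1 (0.136) or 2 (0.0532) or KO RS replicate 3 (0.113). Of 22 Sertoli genes 14 were higher (20 higher and 1 lower adjusted over the list alone, median 3.96, camera adjusted p = 1.38e-09) and of 15 Leydig genes 9 (10 adjusted over the list alone, median 2.74, camera adjusted p = 2.93e-05), with an adjusted p of 0.506 for both with an estimated correlation. The list of macrophages, other leukocytes and blood had 2 of 15 higher (5 adjusted over the list alone, median 1.24, camera adjusted p = 0.0332, and adjusted p = 0.723 with an estimated correlation). It was lost without WT RS replicate 2 (0.0576) or the library labelled KO RS replicate 1 (0.139).

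Genes that act on mRNA tails and mRNA decay changed in both directions in round spermatids, and none of their lists passed camera. Of 24 deadenylase genes, Tob2, which recruits the CCR4-NOT deadenylase, was the 1 lower (also 1 adjusted over the list alone, median -0.09, camera adjusted p = 0.31), at -0.86 (adjusted p = 0.0105) and 0.0666 without the library labelled KO RS replicate 1. Of 39 poly(A) binding and polyadenylation genes, 4 were higher and 7 lower (5 and 7 adjusted over the list alone, median -0.08, camera adjusted p = 0.597). Cstf2t, a cleavage factor of germ cells, fell by 0.91 on the log2 scale (adjusted p = 0.00316). Of 22 decapping genes 4 were lower (5 adjusted over the list alone, median -0.13, camera adjusted p = 0.428), among them Edc4 (-1.26, adjusted p = 0.00189) and Dcp1a (-1.05, adjusted p = 0.00568), both parts of the decapping complex. Exosome and nonsense-mediated decay genes had 1 of 27 higher and 4 lower (1 and 6 adjusted over the list alone, median -0.07, camera adjusted p = 0.31), with Smg9 at -1.12 (adjusted p = 0.00406). Translational control genes had 3 of 48 higher and 7 lower (3 and 9 adjusted over the list alone, median -0.07, camera adjusted p = 0.386). Translation factors had 2 of 54 higher and 4 lower (2 and 4 adjusted over the list alone, median 0.02, camera adjusted p = 0.92). The piRNA pathway genes had 1 of 29 higher and 5 lower (3 and 6 adjusted over the list alone, median -0.08, camera adjusted p = 0.69). Piwil1, a PIWI protein that binds piRNAs and a member of both the translational control and the piRNA list, fell by 0.78 on the log2 scale (adjusted p = 0.00483).

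The lists of metabolic, structural and stress genes did not pass camera in round spermatids. The flagellum list had 11 of 122 higher and 10 lower (14 and 10 adjusted over the list alone, median 0.06, camera adjusted p = 0.446), with Catsper3, a sperm calcium channel subunit, at 0.77 (adjusted p = 0.00586). The mitochondrial sheath and energy list had 6 of 42 higher and 2 lower (7 and 3 adjusted over the list alone, median 0.06, camera adjusted p = 0.356). Slc2a3, a glucose transporter, fell from 440 ± 135 to 158 ± 18.1 CPM (-1.48, SE 0.188, adjusted p = 6.69e-05). Oxidative phosphorylation genes had 1 of 75 higher and 5 lower (1 and 4 adjusted over the list alone, median 0.11, camera adjusted p = 0.519), with Atp5d at -1.06 (adjusted p = 0.000583), and the 13 mitochondrially encoded transcripts had 0 called (also 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.518). Stress response genes had 2 of 32 higher and 8 lower (3 and 9 adjusted over the list alone, median -0.07, camera adjusted p = 0.225), with Herpud1, a factor of endoplasmic reticulum stress, at 60.9 ± 5.29 and 19.2 ± 0.553 CPM (-1.66, SE 0.157, adjusted p = 4.43e-06) and the stress transcription factor Atf4 at -0.91 (adjusted p = 0.00341). Germ cell transcription factors had 5 of 35 higher and 6 lower (8 and 8 adjusted over the list alone, median 0.10, camera adjusted p = 0.902), with Rfx8 at -1.19 (adjusted p = 0.000362). The p53 and apoptosis list had 3 of 30 lower (2 adjusted over the list alone, camera adjusted p = 0.779), with a median of 0.09 while the test pointed down. Ubiquitin, proteasome and autophagy genes had 3 of 59 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.05, camera adjusted p = 0.607). Meiotic prophase genes had 2 of 47 higher and 3 lower (also 2 and 3 adjusted over the list alone, median -0.09, camera adjusted p = 0.92). Spermatogonia markers had 3 of 20 higher and 1 lower (also 3 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.31). Leptotene to pachytene markers had 2 of 22 higher and 2 lower (also 2 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.775). Peritubular myoid, endothelial and stromal genes had 2 of 18 higher (also 2 adjusted over the list alone, median 0.81, camera adjusted p = 0.143).

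**Figure D5:**
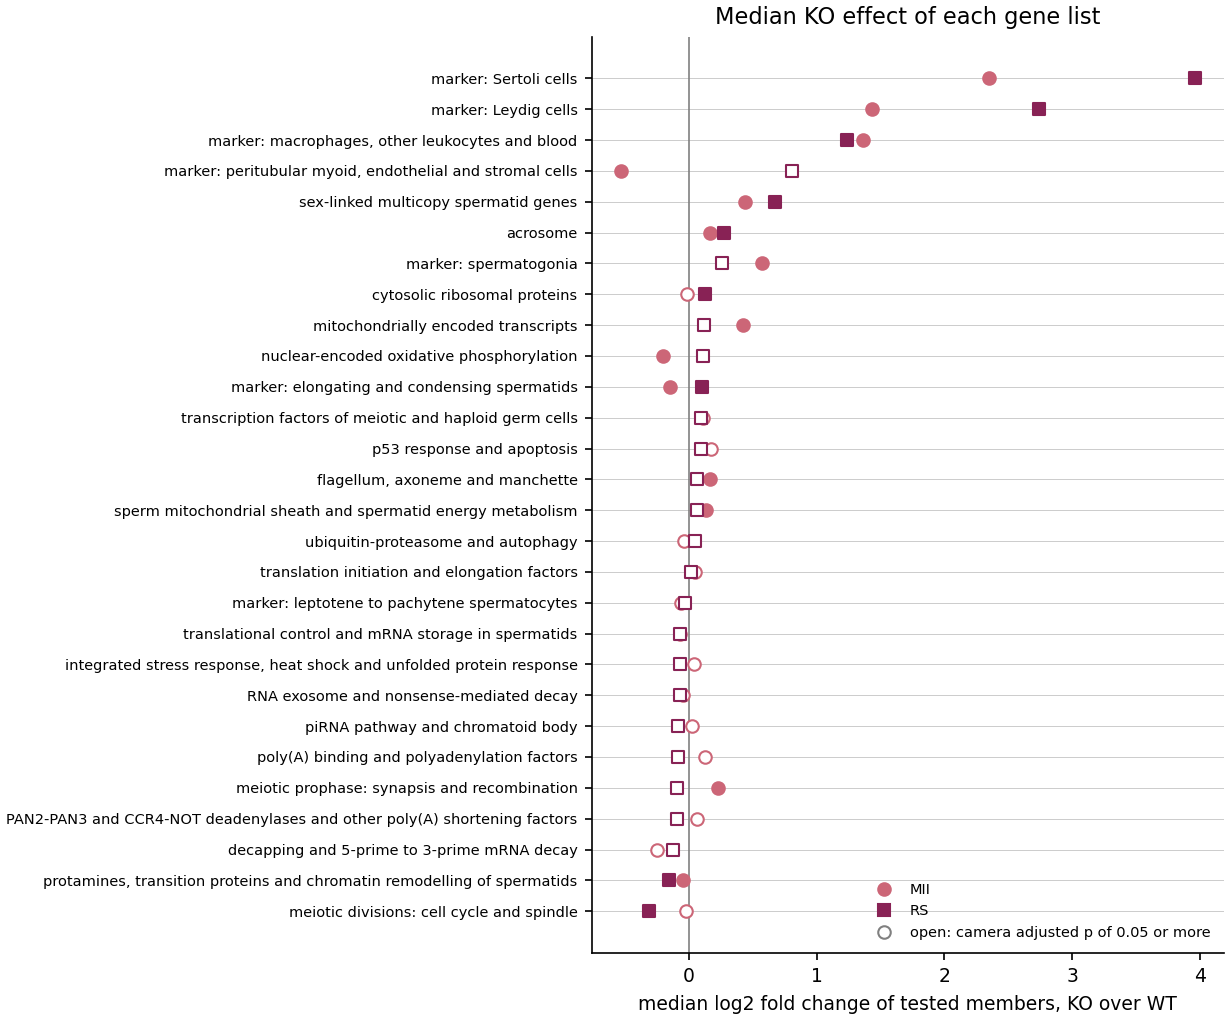
Median log2 fold change of the tested members of each of the 28 gene lists, KO over WT, in MII (circles) and RS (squares). Filled symbols have a camera adjusted p under 0.05 with the preset correlation. Sertoli markers stand highest, at 2.35 in MII and 3.96 in RS, and meiotic division genes lowest in RS, at -0.31.

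The last KO comparison asked whether the effect differed between the stages, which share no library. The sorted fractions may still share cells, as markers of elongating and condensing spermatids summed to 11200 CPM in WT MII and 12900 CPM in WT RS libraries. Across the 21291 genes the log2 fold changes correlated at r = 0.563 and rho = 0.519 (genes are not independent replicates). Of the 784 genes called in MII, 771 had the same sign in RS. Both stages called 262 genes higher, against 23.6 for independent lists, and 277 lower, against 29.2, and 0 genes were called in opposite directions. The test of the difference itself called 1 gene, Acta2, whose change was 3.04 larger (log2, SE 0.44, adjusted p = 0.0269) in RS than in MII. It had 32.8 ± 16.0 CPM in WT and 6.77 ± 2.69 CPM in KO MII libraries, and 3.09 ± 0.474 and 5.25 ± 1.31 CPM in WT and KO RS libraries. At an unadjusted p under 0.05 there were 1405 genes, DESeq2 called 21 and limma-voom 0. The call of Acta2 was lost without WT MII replicate 1 (0.0794), KO MII replicate 2 (0.0988) or 3 (0.0566), WT RS replicate 1 (0.102), 2 (0.17) or 3 (0.215), or KO RS replicate 2 (0.0843), and 2 genes were called without WT MII replicate 2 or without the libraries labelled KO RS replicate 1 or replicate 3. Of the 28 gene lists, 10 passed camera for the difference and 0 with an estimated correlation (adjusted p between 0.167 and 0.642).

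From the MII stage to round spermatids in WT mice, some genes of chromosome synapsis and cell division fell, and some of the sperm tail and acrosome rose. Sycp3, a protein of the synaptonemal complex that holds paired chromosomes together, fell from 90.7 ± 34.6 to 29.9 ± 9.06 CPM (n = 3, log2 fold change -1.60, SE 0.248, edgeR adjusted p = 0.000361), and Hormad1, of the same axis, by 1.27. Rec8, a meiotic cohesin of that axis, rose from 55.5 ± 7.77 to 113 ± 13.9 CPM (1.03). The cell cycle kinase Cdk1 fell by 1.55 and Sgo2a, which protects sister chromatid cohesion, by 1.33 on the log2 scale. Akap3, a protein of the sperm fibrous sheath, rose by 0.94, Spag6, of the axoneme, by 0.78, and Fam170b and Actl7a, of the acrosome, by 0.80 and 0.72. Among the 8 largest rises by the fixed rule were those of Ap2a1 (1.81, from 11.8 ± 1.5 to 41.3 ± 3.23 CPM), Ace3 (1.80), Znrf4 (1.53) and Ccnd3 (1.52). Among the 8 largest falls were those of Ube2t (-2.47), Pcbp1 (-2.01) and Calm2 (-1.98). Adjusted p for the genes of this paragraph lay between 5.68e-06 and 0.0068, and every call held without any 1 library.

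In all, 1648 genes were higher and 1849 lower in WT round spermatids than in WT MII spermatocytes (3497 of 21291), with 1312 changed at least 2-fold (429 up and 883 down). Of 84 cytosolic ribosomal proteins 40 were lower and 0 higher (56 and 0 adjusted over the list alone, median -0.39, camera adjusted p = 3.02e-15), for example Rps27a (-1.20, adjusted p = 7.29e-05). Of 75 oxidative phosphorylation genes 39 were lower and 0 higher (47 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 5.24e-10), with Ndufc2 at -1.52 (adjusted p = 2.6e-05) and Sdhd at -1.14 (adjusted p = 0.00086). Flagellum genes had 32 of 122 higher and 10 lower (41 and 12 adjusted over the list alone, median 0.21, camera adjusted p = 6.92e-05). The adjusted p of these 3 lists was 0.245, 0.517 and 0.201 with an estimated correlation. Division genes had 13 of 56 lower and 2 higher (15 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.00166, and adjusted p = 0.685 with an estimated correlation). It was lost without WT MII replicate 2 (0.116) or WT RS replicate 2 (0.0869). Elongating spermatid markers had 5 of 20 higher (7 adjusted over the list alone, median 0.31, camera adjusted p = 0.0376, and adjusted p = 0.794 with an estimated correlation). It was lost without WT MII replicate 1 (0.0798) or 2 (0.221) or WT RS replicate 2 (0.539). Meiotic prophase genes had 3 of 47 lower and 2 higher (also 3 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.564) and acrosome genes 8 of 67 higher and 3 lower (also 8 and 3 adjusted over the list alone, median 0.07, camera adjusted p = 0.107), so neither list passed. The count of 3497 was 2010 without WT MII replicate 3 and 1776 and 2207 without WT RS replicate 1 and 2, and 2108 when only the 6 WT libraries were fitted.

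Leydig, peritubular myoid, endothelial and stromal markers fell between the stages in WT mice. Of 15 Leydig genes 12 were lower (14 adjusted over the list alone, median -5.05, camera adjusted p = 1.74e-20), Fabp3 among them at -6.12 (SE 0.517, adjusted p = 2.73e-06). Of 18 peritubular myoid, endothelial and stromal genes 12 were lower (12 lower and 1 higher adjusted over the list alone, median -3.38, camera adjusted p = 8.86e-15), including Acta2 (-3.40, SE 0.326) and Dcn (-5.66, SE 0.898, and -7.41 without WT RS replicate 2). Both lists passed with an estimated correlation (adjusted p = 0.043 for each). Sertoli genes had 5 of 22 lower (7 adjusted over the list alone, median -2.44, camera adjusted p = 0.00247, and adjusted p = 0.685 with an estimated correlation). The list of macrophages, other leukocytes and blood did not pass (median -0.45, camera adjusted p = 0.781), and its summed CPM was 23.2 in WT MII and 21.2 in WT RS libraries.

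From MII to RS in KO mice, 25 of 56 meiotic division genes and 16 of 84 genes of ribosomal proteins were lower in round spermatids (adjusted p = 0.318 and 0.328 with an estimated correlation). In all, 885 genes were higher and 1740 lower (2625 of 21291), with 1055 changed at least 2-fold (88 up and 967 down). Scaling by the total count alone gave 601 higher and 1955 lower. The count was 1669, 1559 and 1682 without KO MII replicate 1, 2 and 3, 1680 (359 higher and 1321 lower) and 1096 (225 and 871) without the libraries labelled KO RS replicate 1 and 2, and 4451 (2074 and 2377) when only the 6 KO libraries were fitted. Division genes had 25 of 56 lower and 0 higher (30 and 0 adjusted over the list alone, median -0.55, camera adjusted p = 5.56e-13). Ribosomal proteins had 16 of 84 lower and 0 higher (17 and 0 adjusted over the list alone, median -0.22, camera adjusted p = 9.32e-07), and Leydig genes 12 of 15 lower (13 adjusted over the list alone, median -3.71, camera adjusted p = 8.89e-23). The adjusted p of these lists was 0.318, 0.328 and 0.0465 with an estimated correlation. In all, 15 of the 28 lists passed camera in KO mice and 8 in WT mice, and 1 and 2 with an estimated correlation. The stage changes of WT and KO libraries correlated at r = 0.624 and rho = 0.568 across genes, with 568 genes higher and 987 lower in both, against 68.5 and 151 for independent lists, and 0 in opposite directions.

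Whether KO libraries sat nearer to the other stage was described from the genes that changed between stages in WT, which share their WT libraries with the KO comparison. In MII, the 1648 genes that rise towards RS had a median KO effect of 0.26 and the 1849 that fall -0.28 (log2). In 20 simulated data sets without a KO effect the medians lay between 0.07 and 0.10 and between -0.10 and -0.07. In RS, the observed medians were -0.04 and -0.05, against -0.08 to -0.07 and 0.07 to 0.10 in the simulations. Simulated genes were drawn independently, so spread that many genes of a library share is missing and the simulated ranges may be too narrow. The simulations also called more stage genes than observed, at a median of 2340 rising and 2550 falling. With stage genes taken from the KO libraries, the RS medians were 0.27 and -0.49.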

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

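The tests of the Pan2 count, and those of the protamine genes against elongating spermatid markers and GC content, were chosen after the result was seen, while the test on short transcripts and the counts of other splits were chosen before.

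The test of the difference between the KO effects of the stages picked out Acta2, an actin of smooth muscle and myoid cells, whose log2 effect was 3.04 larger in RS than in MII (edgeR adjusted p = 0.0269). The same contrast picked out 10 gene lists by camera. Lower log2 effects in RS than in MII were found for deadenylases (median difference -0.21, camera adjusted p = 0.0427), poly(A) binding and polyadenylation factors (-0.13, 0.0427), flagellum genes (-0.13, 0.0353), meiotic prophase genes (-0.17, 0.0427) and meiotic division genes (-0.28, 6.58e-06). Higher ones were found for ribosomal proteins (0.14, 4.34e-05), oxidative phosphorylation genes (0.30, 6.58e-06), and the markers of Sertoli cells (1.42, 0.0392), Leydig cells (1.495, 0.0427) and peritubular myoid, endothelial and stromal cells (1.02, 3.42e-10). None of the 10 passed camera with an estimated correlation (adjusted p between 0.167 and 0.642).

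The calls of the ribosomal, division and myoid lists for this difference held without any 1 library, and those of the other 7 did not. The oxidative phosphorylation call was lost without WT MII replicate 3 (0.0534), and the flagellum call without that library (0.137) or the library labelled KO RS replicate 1 (0.104). The deadenylase call was lost without WT MII replicate 3 (0.219), KO MII replicate 1 (0.0908) or 2 (0.0628), WT RS replicate 1 (0.0586) or 3 (0.103), or the libraries labelled KO RS replicate 1 (0.0657) or 2 (0.143). The poly(A) call was lost without WT MII replicate 3 (0.172), KO MII replicate 1 (0.0908), WT RS replicate 3 (0.108), or the libraries labelled KO RS replicate 1 (0.0643) or 2 (0.077). The prophase call was lost without WT MII replicate 2 (0.121) or 3 (0.0568), KO MII replicate 1 (0.17) or 2 (0.124), WT RS replicate 3 (0.108), or KO RS replicate 2 (0.146) or 3 (0.0591). The Sertoli call was lost without WT MII replicate 2 (0.136) or 3 (0.0534), KO MII replicate 2 (0.0984) or 3 (0.139), WT RS replicate 2 (0.107) or the library labelled KO RS replicate 1 (0.381). The Leydig call was lost without WT MII replicate 1 (0.0678) or 2 (0.144), KO MII replicate 2 (0.106) or 3 (0.0906), WT RS replicate 2 (0.265) or 3 (0.0681), or the libraries labelled KO RS replicate 1 (0.464) or 2 (0.077). Other settings ended calls too: the deadenylase call was lost with the replicate block (0.062), the stricter filter (0.0573) and the marker covariates (0.0789), the poly(A) and flagellum calls with the covariates (0.0745 and 0.0925), the prophase call with the stricter filter (0.0837), and the Sertoli and Leydig calls without a filter (0.0663 and 0.0902).

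Other splits of the libraries were counted for each comparison. For the difference, 5 of 100 drawn splits (of 200 possible), the real one included, called at least as many genes as the real 1, so chance is not excluded. The highest other split called 2332 genes and 3 others 345, 329 and 263. These 4, like 6 other drawn splits that called 0 genes, keep the RS libraries parted by genotype and mix the genotypes in MII. The difference between genotypes in RS is a structure of the samples that enters such splits, so they are no clean reference for chance, and what sets the 4 apart from the 6 was not tested. For single comparisons the 10 splits are too few for a share under 0.05. Each other split also puts libraries of both real groups on either side. The real difference then adds to the spread and lowers the calls, so these counts are no clean reference for chance either. The real split was the 1 with the most calls in each: KO against WT called 784 genes in MII and 2863 in RS, each with 0 in the highest other split, and RS against MII called 3497 in WT and 2625 in KO, with 14 and 2 in the highest other split.

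Pan2 stood at 22.57 CPM in the library labelled KO RS replicate 1, against 4.73 and 3.52 CPM in the other libraries of its group. A WT library under a KO label is argued against, since over the 784 genes called in MII the library deviated from the WT RS mean with a slope of 0.761 on the MII effect (95% bootstrap interval 0.695 to 0.835), beside 0.672 and 0.714 for the other KO RS libraries and -0.0492 to 0.0379 for WT RS libraries. The WT RS libraries are part of that mean, so their slopes lie around 0 by construction. RNA of Sertoli, Leydig or other testis cells is also argued against as the source, because KO MII replicate 1 had larger marker sums on all 5 lists of such cells and spermatogonia, and 5.57 CPM of Pan2, within the 5.07 to 7.10 CPM of the other KO MII libraries. Germ cells that kept the floxed allele are argued against as the whole source, as 1 intact allele would not exceed the WT level, and 22.57 CPM lies above the 8.13 to 12.95 CPM of WT RS libraries and their mean plus 3 SD (17.6 CPM). Reads from exons outside the floxed part would be in every KO library, and the other 5 had at most 7.10 CPM. What raised the count in this library stays open.

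The protamine and transition protein genes Prm1, Prm2, Prm3, Tnp1 and Tnp2 had a median log2 fold change of -2.23 in the RS libraries, with Prm3 not lower (0.21). The other 15 tested markers of elongating and condensing spermatids had a median of 0.156 (median absolute deviation 0.222), so the fall was not common to the list. Camera for the whole list pointed down. Its members with the highest CPM in KO RS libraries, Smcp, Dnajb3 and Pgam2, differed little between WT MII and WT RS libraries. They stood at 1090 and 1160, 1170 and 1170, and 1110 and 1060 CPM. Whether such markers follow the content of elongating spermatids is not known, so they cannot decide whether fewer of these cells caused the fall. Across 14060 autosomal coding genes the log2 fold change fell as GC content rose (Spearman -0.259 in RS and -0.144 in MII). The RS median was 0.11 in the group of lowest GC content and -0.308 in that of highest. GC content and short transcripts are argued against as the whole cause: 6253 autosomal coding genes of the same GC range had a median of -0.148 (deviation 0.349), and 374 genes no longer than the longest of these had 0.106 (deviation 0.368). Fewer elongating spermatids among the sorted cells or a shift towards earlier steps among round spermatids may account for the fall. So may a lower capture of transcripts by oligo(dT) priming or an effect of PAN2 on the level of these mRNAs, and all stay open as hypotheses.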

How the results depend on the processing

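The covariates of Sertoli and Leydig scores, the counts of protein-coding genes, and the list tests other than with an estimated correlation, fry, the replicate block and DESeq2's size factors were chosen after the data were seen, and the other alternatives of this part before. Counts of called genes in KO against WT stayed within 1.5 times of 784 in MII and 2863 in RS under DESeq2's size factors, the total count, the stricter filter, limma-voom and the omission of mitochondrial and top genes. Of the called genes of the named-gene rule that were followed in each fit, 13 of 42 in MII, 32 of 46 in RS and 23 of 23 in RS against MII in WT passed in all 12 fits that each left out 1 library. The covariates ended 34 of these 42 calls in MII and 33 of the 46 in RS, and the fit to only the 6 libraries compared ended 16 in MII and 0 in RS. In MII the total count ended 4, limma-voom and the replicate block 2 each, and DESeq2 and the absence of a filter 1 each. In RS the absence of a filter ended 3, the replicate block 2, and the total count and limma-voom 1 each. The stricter filter, which tested 37 of the 42 and 45 of the 46, ended 0. For all changes that follow, the cause was not tested, except that a fold threshold calls fewer genes by construction. In simulated counts with 200 genes changed, most small changes were missed: of genes changed 1.5-fold, 5.97% were recovered in MII and 10.8% in RS. The real comparisons called more genes, 784 and 2863, which makes the adjusted threshold less strict. These shares therefore do not carry over to them. Depth was not varied on its own.

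For KO against WT in MII the count was 1440 without a filter, 403 with only the 6 libraries compared, 40 with the marker covariates, 1455 with DESeq2, 375 at a fold change of at least 2, and 147 to 976 when each library was left out. In RS it was 106 with the covariates, 1177 at the fold threshold and 1080 to 3573 without single libraries. The difference, with 1 call, had 65 without a filter, 0 with the stricter filter, 3 with the covariates, 0 with limma-voom, 21 with DESeq2 and 0 to 2 without single libraries. RS against MII had 2108 (6 libraries), 1312 (fold threshold) and 1776 to 3980 (single libraries) in WT, and 4451, 1055 and 1096 to 3286 in KO.

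Of gene lists, camera called 14 in MII, 9 in RS, 10 for the difference, 8 for RS against MII in WT and 15 in KO. With an estimated correlation these were 0, 0, 0, 2 and 1. With fry they were 6 in MII, 1 in RS and 0 for the difference, with the covariates 7 in MII, and without a filter 13 in WT. Without single libraries the ranges were 10 to 14 in MII, 6 to 9 in RS, 5 to 12 for the difference, 6 to 13 in WT and 13 to 19 in KO.

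With the covariates, which separate the genotypes and raise the median SE by 1.68 times in MII and 1.84 times in RS, the direction turned for spermatogonia (camera adjusted p = 0.406), Leydig cells (0.247) and macrophages, other leukocytes and blood (0.247) in MII and for the last of these in RS (0.139). So it did for the log2 fold changes of Cyp11a1 (-1.20) and Amhr2 (-0.06, -0.0612) in MII and of Gstm1 (-0.33, -0.334), Prm3 (-0.21, -0.209) and Dazl (-0.03, -0.0297) in RS. The value of Prm3, KO vs WT in MII, at -0.20, was -0.473 to 0.155 without single libraries, and above 0 without WT MII replicate 3. Pan2 in MII, at -1.28, was -3.10 with the covariates. Pan2 in RS, at 0.003, was -0.06 (-0.0562) with the total count, -2.53 with the covariates, -0.42 (-0.421) with limma-voom, -0.01 (-0.0104) with DESeq2 and -1.32 to 0.407 without single libraries.

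Beside the estimated correlation, fry and left-out libraries, some settings ended camera calls of single lists. In MII these were the protamine list without a filter (0.115), the mitochondrial sheath list with 6 libraries (0.076) and the covariates (0.206), mitochondrially encoded transcripts with the covariates (0.592), prophase genes with the total count (0.0515), the stricter filter (0.497), 6 libraries (0.0715) and the covariates (0.613), spermatogonia with the stricter filter (0.843) and Sertoli cells with the covariates (0.634). In RS they were ribosomal proteins with the covariates (0.333), Leydig cells with 6 libraries (0.0567) and the covariates (0.43), and macrophages, other leukocytes and blood with 6 libraries (0.15). Between stages they were elongating spermatid markers in WT with the stricter filter (0.138) and 6 libraries (0.0554), and in KO flagellum genes with the total count (0.0818) and the stricter filter (0.11) and sex-linked genes with the stricter filter (0.104).

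The correlation of KO effects between stages was 0.692 over genes with a mean of at least 5 CPM, against 0.563. With stage genes taken from KO libraries the RS medians along the stage change were 0.269 and -0.492, against -0.0444 and -0.049.

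The replicate numbers were not taken to pair the libraries, since in no pair of groups did all 3 same-numbered pairs correlate above 0.1 in their deviations. The correlations were -0.143 to 0.0445 for KO and WT in MII, 0.0101 to 0.155 in RS, -0.203 to 0.0377 for MII and RS in WT, and 0.287, 0.0836 and 0.155 in KO. In KO these were positive and 5 of the 6 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block the counts were 760 in MII, 2902 in RS, 2 for the difference, 2908 in WT and 2127 in KO, and Pan2 in RS was at -0.45 (-0.451). Of list calls, the block ended 1, that of deadenylases for the difference (0.062).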

Other observations

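The tests on the X chromosome and the genes of this part were chosen after the result was seen. The test with marker covariates was chosen after the data were seen but before its own result for X-linked genes.

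X-linked genes were higher in KO libraries of both stages. The 790 tested X-linked genes had a median log2 fold change of 0.48 in MII, with 87 genes higher and 0 lower, and of 0.67 in RS, with 238 higher and 2 lower. The 281 Y-linked genes, many of them multicopy and uncertain because they may share reads, had medians of 0.26 and 0.73, with 5 and 44 higher and 0 lower. Autosomal genes had medians of -0.02 and -0.04, and the medians of single autosomes lay between -0.07 and 0.03 in MII and between -0.13 and 0.07 in RS. With an estimated correlation camera gave p = 0.0172 in MII and 0.00926 in RS for the X chromosome and 0.424 and 0.125 for the Y chromosome. In every KO library the X median exceeded the autosomal one (0.602, 0.569 and 0.324 in MII, and 0.752, 0.682 and 0.542 in the libraries labelled KO RS), while WT libraries lay between -0.182 and 0.138. Values per library are against the WT mean of the stage, which includes each WT library, so WT values lie around 0 by construction. For the Y chromosome the groups overlapped in MII (0.09, 0.697 and 0.191 in KO, and -0.116, -0.23 and 0.437 in WT) and not in RS (0.489 to 0.877 in the libraries labelled KO, and -0.201 to 0.148 in WT).

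X-linked genes exceeded autosomal genes by 0.501 (95% bootstrap interval over genes 0.462 to 0.539) in MII and 0.707 (0.656 to 0.763) in RS. The intervals of this paragraph resample genes, which are not independent replicates, and leave out the spread between libraries given above. GC content is argued against as the whole cause, since against autosomal genes of the same GC content the difference was 0.641 (0.573 to 0.679) in RS and 0.459 (0.42 to 0.512) in MII. A shift of KO libraries towards the other stage is argued against too, because from MII to RS in WT the difference was 0.0211 (-0.048 to 0.0712). RNA of Sertoli and Leydig cells cannot be told apart from the genotype for X-linked genes as a whole (0.494 in RS and 0.292 in MII with both marker scores as covariates, which separate the genotypes). The 23 sex-linked multicopy spermatid genes had medians of 0.677 (0.502 to 0.734) in RS and 0.441 (0.272 to 0.582) in MII. This argues against such RNA for them only so far as they are genes of spermatids, as the fixed list names them. Their expression in other testis cells was not checked, and RNA of earlier germ cells was not tested as a source. A weaker silencing of the sex chromosomes in KO cells may be a hypothesis to follow and was not tested. It would have to cover the MII libraries too, where the excess was 0.501.

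The lowest adjusted p in both stages was that of 3110070M22Rik, outside the named-gene rule, a protein-coding gene on chromosome 13 (119487252 to 119488384, minus strand). It went from 141 ± 13.8 to 0.737 ± 0.207 CPM in MII (log2 fold change -7.59, edgeR adjusted p = 8.28e-15) and from 160 ± 3.65 to 0.786 ± 0.156 CPM in RS (-7.65, adjusted p = 6.6e-15). Genes of the kallikrein cluster on chromosome 7, which may share reads with each other and are uncertain, did not all go one way. Lower in both stages were Klk1b26 at -3.50 and -3.67 (adjusted p = 9.7e-05 and 1.13e-05), Klk1b9 at -3.24 and -2.72 (adjusted p = 0.00167 and 0.00188, with -3.64 in RS without KO RS replicate 2) and Klk1b8 at -2.18 and -2.38 (adjusted p = 0.000695 and 6.04e-05). Klk1 (-2.43 and -1.87, adjusted p = 0.0184 and 0.0205) lost its call in MII without WT MII replicate 3 (0.0716) or KO MII replicate 1 (0.0587), 2 (0.0534) or 3 (0.0604), and in RS without WT RS replicate 1 (0.0531) or 2 (0.0533) or the libraries labelled KO RS replicate 2 (0.0934) or 3 (0.0704), and its RS value was -2.84 without the library labelled KO RS replicate 1. Klk1b21 and Klk1b24 were higher in KO MII libraries, at 1.61 ± 0.654 and 0.831 ± 0.269 CPM against 0.189 ± 0.199 and 0.0201 ± 0.0348 CPM in WT (adjusted p = 0.0379 and 0.0212). Both were at 0 CPM in the libraries labelled KO RS. The Leydig marker sum was 567, 340 and 296 CPM in KO MII and 169, 156 and 162 CPM in WT MII libraries, and whether these 2 genes follow it was not tested. The call of Klk1b21 was lost without WT MII replicate 2 (0.0833) or 3 (0.136) or KO MII replicate 1 (0.16) or 2 (0.161). That of Klk1b24 was lost without WT MII replicate 1 (0.0503), 2 (0.057) or 3 (0.0553) or KO MII replicate 1 (0.083) or 2 (0.111), and both calls ended with the marker covariates.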
